A study of Danio rerio with 4 samples.

How the data were processed

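Ovarian follicles of zebrafish (Danio rerio, strain AB, 3 months old) at the primary growth and pre-vitellogenic stages were sorted by size and morphology, per the labels' protocols. RNA was extracted with column kits for small and for regular RNA, and TruSeq and small RNA libraries were sequenced on an Illumina HiSeq instrument, paired-end for mRNA and single-end for small RNA, per the labels' protocols. Whether mRNA was selected by its poly(A) tail, and whether follicles of several fish were pooled, is not given in the sources used here. The 4 libraries were grouped by their cell type label, since all 4 titles read PG. The table columns named PG and PV were matched to the labels of primary growth and pre-vitellogenic follicles.

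The mRNA values are FPKM per transcript with a lower and upper bound and a status mark, as deposited by the authors. The submitters' processing notes name TopHat2 2.0.11, Cufflinks 2.2.1 and the Zv9 build without saying at which step each was used. Rows carry Ensembl transcript and gene IDs, gene names and coordinates. In the primary growth library 10 rows of 4 gene names were marked as failed estimates, and none in the other. Gene names were those of the table; 21938 of the 33734 gene IDs were found in a table of current symbols, which, with RefSeq synonyms of the assembly GRCz12tu, was used only to match names of gene lists. Rows of the same gene name were summed to 29435 names, so a name shared by several gene IDs holds all of them. The length of a gene is the mean of its transcripts' lengths weighted by FPKM.

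The small RNA table's header says RPKM. In it every value above 0 was a whole multiple of 1 step per library, whatever the length of the miRNA, with a tolerance of 0.01 steps, so the deposited values were read as RPM of a library total. The step was 0.0761 RPM in primary growth and 0.0525 RPM in pre-vitellogenic follicles, which gives totals of 13147324 and 19043107 reads. What these totals count, and how the authors mapped and counted small RNA reads, is not given in the sources used here. Reads per miRNA were the value divided by the step. Wilson intervals for shares and exact conditional intervals (Clopper-Pearson) for ratios were taken from these reads at the 95% level; they cover counting error only. Recovery of read numbers was tested on simulated data, where all 50 simulated libraries gave back every read number. Each held consecutive low read numbers, which fix the step, and no read was counted more than once. The simulation thus covers the arithmetic of the step and not whether the numbers are single reads.

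With 1 library per stage and kind, no test across stages was possible. Each item is given by its value in both libraries and by the log2 difference of pre-vitellogenic over primary growth follicles, on the log2(value + pseudocount) scale, which understates the difference of low items. The pseudocount was 1 FPKM for mRNA and 10 RPM for miRNA. Genes at 1 FPKM or more and miRNAs at 100 RPM or more in the higher library were compared, and called higher or lower at a 2-fold difference. Nothing was rescaled in the main values. An exact 0 in FPKM can be a failed estimate, so such items are only said to be listed at 0.

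Fixed before the data were examined were 27 gene lists, 26 miRNA lists, the rules above and the rule for named items. That rule took the 12 genes with the largest difference in each direction among those at 5 FPKM or more without a clone name, up to 4 members per list, the 5 most abundant genes of each library, and a set of ovarian genes whatever their values. For miRNAs it took the 8 largest per direction, the 5 most abundant and list members. Some genes of these groups were left out of the text, 1 gene among the largest differences is not reported here, and others, given for contrast within their list (cyp11a1, cyp17a1, cyp17a2, hsd17b3, hsd17b4, bmp6, nrg1, tsc1b, tsc2, eif4ebp1, sox11b, eomesa and foxh1) or for their separate intervals, were named after their values were seen. A list's median difference was set against 10000 random lists of the same size matched on mean expression in 20 bins, and its percentile describes these 2 libraries only. Some genes stand on several lists, for example zar1, btg4, inha, inhbaa, amh and igf1rb, so the lists are not independent. Matching on expression and transcript length, in 10 bins of each, was added after a trend with length was seen. In simulated data on 14473 genes, 3 of 60 unchanged lists of 20 genes lay beyond percentile 2.5 or 97.5 by either matching, and all 60 lists shifted by 1 lay above. Of 60 unchanged lists of long genes under a simulated length trend, 40 lay above the upper mark by expression matching while by expression and length 1 lay above it and 4 below the lower mark. The simulated noise was independent between genes and of the same spread at every expression level. These rates may therefore not hold for lists whose genes vary together.

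Alternatives tried were other pseudocounts, filters and fold rules, rescaling to the same FPKM total or by the 75th percentile, centring on the median, the most abundant row per gene name, leaving out rows marked as failed, and for miRNAs rescaling to the same total with and without the most abundant miRNA. Those added later removed the length trend, used protein-coding genes alone, left out mitochondrially encoded genes, or, for sums of miRNA lists, took values of 0 as 5 reads or counted a sequence listed under 2 names once. The planned search for seed sites of miRNAs in 3' UTRs, which would pair miRNAs with targets, was not run here, since no 3' UTR sequence was used. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.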

Results

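The series set out to find the miRNAs, and the transcripts they might target, that differ as zebrafish ovarian follicles are activated. Follicle activation is the step from the primary growth stage, in which the oocyte is small and enclosed by a thin follicle layer, to the pre-vitellogenic stage, which precedes yolk uptake. Follicles of both stages were sorted by size and morphology from ovaries of 3-month-old fish of the AB strain. Each stage gave 1 small RNA library and 1 mRNA library, so 4 libraries were compared as 2 pairs. There were no replicates, and no difference below has a replicate check. No p-value or standard error is given. The sample titles call all 4 libraries PG, whereas the cell type labels and the column names of the tables separate primary growth from pre-vitellogenic follicles. The cell type labels were followed here.

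The mRNA table held 56711 transcripts of 33734 Ensembl gene IDs on the Zv9 build, in FPKM. Transcripts above 0 FPKM numbered 32066 in the primary growth library and 33985 in the pre-vitellogenic library. Summed FPKM was 730172 and 608220, and the read depth of these libraries is unknown. The small RNA table listed 118 mature miRNAs, 76 of them above 0 in primary growth follicles and 107 in pre-vitellogenic follicles. The step between its values corresponds to library totals of 13147324 and 19043107 reads.

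The first comparison asked which transcripts differ between the stages. Relative to primary growth follicles, the pre-vitellogenic library held more RNA of the mitochondrial genome and of the lists for TGF-beta, activin and BMP signalling and, with members below 5 FPKM counted, for EGF, IGF and KIT ligands and receptors. Follicle cell markers, most of them below 5 FPKM, were also higher, short of the percentile mark by expression matching and beyond it with length matched. The hormone receptor list and the PI3K, mTOR, FOXO and Hippo list were higher too, beyond that mark by expression. With length matched the hormone receptor list fell to percentile 83.8, while the PI3K list, at 97.485, was barely short of the mark. The pre-vitellogenic library held less RNA of egg envelope proteins, cytosolic ribosomal proteins and several stored oocyte mRNAs. Of 14473 genes at 1 FPKM or more in the higher library, 4203 were at least 2-fold higher in the pre-vitellogenic library and 945 at least 2-fold lower, on the log2(FPKM + 1) scale. Across these genes Pearson's r between the libraries was 0.896 and Spearman's rho was 0.890, and genes are not independent replicates. The median difference of the 12017 genes at 1 FPKM or more in both libraries was 0.42, in log2 units of pre-vitellogenic over primary growth. After centring on that median, 2193 genes were higher and 1912 lower, so the share of higher genes among those called went from 81.6% to 53.4%. Scaling by the 75th percentile moved that share the same way, to 58.0%, as did removing the length trend with centring, to 56.8%. Other scalings moved it the other way. After rescaling to the same FPKM total 5861 were higher and 711 lower (89.2%), and with mitochondrially encoded genes left out 5836 and 541 (91.5%). Differences of gene groups below are to be read against the median shift of 0.42.

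Differences followed transcript length. Among 13737 protein-coding genes the median difference was -0.17 in the shortest of 10 equal bins of length, with a median length of 531 bases, and 1.20 in the longest bin, with a median length of 5199.5 bases. The share of genes at least 2-fold higher was 18.1% in the shortest bin and 61.9% in the longest. In each of 5 bins of expression the longest bin had a higher median difference than the shortest, for example 0.89 against 0.25 at the lowest expression and 0.86 against -0.64 at the highest. For this reason percentiles of lists are given among random lists matched on expression, and, as a choice made after the trend was seen, among lists matched on expression and length.

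**Figure D1:**
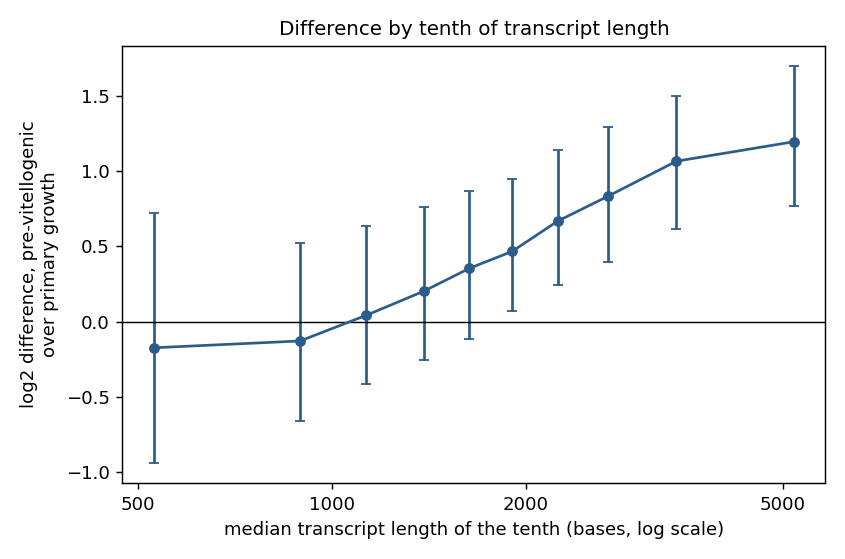
Median log2 difference of FPKM + 1 (y axis, pre-vitellogenic over primary growth) for 10 equal bins of protein-coding genes by transcript length (x axis, bases, log scale). Bars span the lower to the upper quartile of a bin, and the medians go from -0.17 in the shortest bin to 1.20 in the longest.

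Egg envelope genes were lower. Of 17 measured zona pellucida genes, which encode the proteins of the egg coat, 14 were at least 2-fold lower in pre-vitellogenic follicles and none was higher. Their median difference was -1.52, below all 10000 random lists by either matching, and it stayed negative under every scaling tried. The gene zp3.2 (chromosome 17, 2358510 to 2368214) went from 3478 FPKM in primary growth to 993 FPKM in pre-vitellogenic follicles, and zp2.1 from 181.7 to 51.2 FPKM. Near-identical copies within this family make the split of reads between its members uncertain. Of 21775 transcripts at 1 FPKM or more with usable intervals, 6 had deposited confidence intervals that did not overlap between stages. All 6 were lower in pre-vitellogenic follicles, and zp3.2 was among their 5 genes. The other genes, all of them abundant in primary growth follicles, carried the clone names zgc:171781, BX548000.1, CU929143.1 and si:ch211-226h8.14. All 6 had a narrow interval in primary growth, 1806 to 1973 FPKM for zp3.2, whereas that of zp2.1 was 19.1 to 344 FPKM. Their separation rests on these narrow intervals, whose cause is unknown.

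Among 17 genes of the list of oocyte regulators 5 were at least 2-fold lower, none was higher, and the median difference was -0.52. That median lay at percentile 5.92 by expression and 0.38 by expression and length. The counts depended on scaling, with 2 higher and 4 lower (median -0.26) after rescaling to the same FPKM total, and 3 higher and 4 lower (median -0.18) with mitochondrially encoded genes left out. Those lower included h1m, the oocyte linker histone (2338 to 691 FPKM), zar1, an oocyte translation regulator (1086 to 357 FPKM), btg4, an adaptor in maternal mRNA decay (1326 to 471 FPKM), and FOXR1 (85.8 to 29.2 FPKM). The oocyte growth factors were close to level, gdf9 at 56.4 and 62.2 FPKM (difference 0.14) and bmp15 at 117 and 114 FPKM (difference -0.03), and sox11b, eomesa and foxh1 had differences of 0.72 to 0.83, short of the 2-fold mark as deposited. In the list for storage and translation of maternal mRNA, 5 of 25 genes were lower and 2 higher, with a median of -0.37 (percentile 17.7 by expression, 0.115 with length). After rescaling to the same FPKM total 4 were lower and 4 higher (median -0.11), with mitochondrially encoded genes left out 2 and 5 (median -0.03), and after centring 10 and none (median -0.79). Its lower genes included the poly(A)-binding protein genes pabpn1l (388 to 154 FPKM) and pabpc1l (366 to 149 FPKM). Also lower in it were zar1 and btg4, which stand on the oocyte regulator list too. Of 12 genes for meiotic prophase 2 were lower, sycp2 and spo11, and the median was -0.40 (percentiles 0.22 and 0). After centring 6 were lower and none higher, after rescaling to the same FPKM total 2 and 1, and the 4 members at 5 FPKM or more lay at percentile 3.77, short of the mark. The germ plasm and piRNA list had a median of -0.01 over 21 genes, a sign that depended on scaling, with 2 genes lower (henmt1, ca15b) and 1 higher. The higher gene was vasa, the germ-line RNA helicase, at 79.4 and 174 FPKM. After centring none was higher and 6 were lower, and with the length trend removed as well 8 were lower.

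Ribosomal protein genes were lower together. Of 77 measured genes for cytosolic ribosomal proteins 61 were at least 2-fold lower and none was higher, with a median of -1.15, below all 10000 random lists by either matching. Their summed share of all FPKM was 6.16% in primary growth and 3.26% in pre-vitellogenic follicles. The number passing the 2-fold rule depended on scaling, while the median stayed negative. After both libraries were rescaled to the same FPKM total 18 genes were lower and 1 higher. With mitochondrially encoded genes left out 11 were lower, and after centring 76. The largest differences were those of rps18 (480 to 95.1 FPKM) and rpl12 (1485 to 417 FPKM). By contrast, the 30 measured nucleolar genes of ribosome biogenesis had a median of -0.07 (percentiles 53.3 and 11.6), a sign that flipped with scaling, and only nop58 passed the 2-fold rule (53.1 to 139 FPKM).

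Mitochondrially encoded genes showed the opposite. All 13 were at least 2-fold higher in pre-vitellogenic follicles, with a median difference of 3.32, above all 10000 random lists by either matching, that ranged from 2.87 to 3.58 under the scalings tried. Their share of all FPKM was 0.507% in primary growth and 5.77% in pre-vitellogenic follicles. The subunit of complex I encoded by mt-nd5 (mitochondrial genome, 12897 to 14717) was at 37.8 and 596 FPKM, and mt-co1, a subunit of cytochrome oxidase, at 602 and 3638 FPKM. The nuclear genes of oxidative phosphorylation did not go with them. Over 38 of these the median was -0.35 (percentile 1.46 by expression, 26.2 with length), with 1 gene lower, ndufa1, and 1 higher, cox6b1 (0.254 to 3.48 FPKM). After centring 11 were lower and 1 higher. After rescaling to the same FPKM total none was lower and 2 were higher (median -0.09). With mitochondrially encoded genes left out the counts were the same and the median was -0.02.

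Markers of the somatic follicle cells, granulosa and theca, were low and mostly higher in pre-vitellogenic follicles. Of 17 measured genes 11 were at least 2-fold higher and none was lower, with a median of 1.05 (percentile 97.3 by expression, 97.9 with length). After centring 6 were higher, and the 3 members at 5 FPKM or more lay at percentile 61.3. The inhibin alpha subunit gene inha was at 1.25 and 7.31 FPKM, the laminin gene lamb1a at 0.442 and 4.82 FPKM, and the transcription factor gene wt1a at 0.226 and 2.91 FPKM. The gene nr5a1a, a regulator of steroidogenic genes, was listed at 0 in primary growth and was at 2.601 FPKM in pre-vitellogenic follicles. The FSH receptor gene fshr was listed at 0 and was at 1.04 FPKM, amh was at 0.0276 and 1.80 FPKM, and inhbaa at 0.240 and 2.297 FPKM. Values of lhcgr (0.103 and 0.150 FPKM), cyp19a1a (0.315 and 0.370 FPKM), inhbb (0.169 and 0.404 FPKM) and foxl2a, which the table calls foxl2 (0.0337 and 0.273 FPKM), stayed under 1 FPKM in both libraries. The ligand gene kitlga was at 0.403 and 1.18 FPKM.

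Of 15 measured steroidogenic genes 5 were higher and none lower, with a median of 0.47 (percentiles 67.5 and 72.5). The sign of that median rested on low genes, since the 11 members at 5 FPKM or more had a median of -0.16 (percentile 9.3). The largest difference was that of hsd17b1, which converts estrone to estradiol (chromosome 3, 17767912 to 17776090; 0.313 to 14.2 FPKM), followed by hsd3b1 (0.105 to 3.94 FPKM), fdxr and hsd11b2. The side-chain cleavage enzyme gene cyp11a1 was at 119 and 97.2 FPKM and cyp17a1 at 54.1 and 48.3 FPKM. Among less abundant genes hsd17b4 (5.13 and 2.48 FPKM), cyp17a2 and hsd17b3 did not pass the 2-fold rule either, although hsd17b4 was lower by it after centring. Of 14 hormone receptor genes 12 were higher and none lower, and the median of 1.13 lay at percentile 97.6 by expression but 83.8 with length. After centring 4 of the 14 were higher, and with the length trend removed as well 2 (median 0.23). Those higher as deposited included the glucocorticoid receptor gene nr3c1 (1.94 to 13.6 FPKM), igf1rb (3.77 to 15.4 FPKM) and the insulin receptor genes insra (4.16 to 16.8 FPKM) and insrb.

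Lists of growth factor signalling held more genes higher than lower. In the list for TGF-beta, activin and BMP signalling 14 of 29 genes were higher and 2 lower, with a median of 0.93 at percentile 98.85 by expression and 98.97 with length. The activin type II receptor gene acvr2aa (chromosome 9, 26414103 to 26476439) was at 5.25 and 37.0 FPKM and acvr1l at 8.20 and 44.3 FPKM, while bmp6 was lower (8.86 to 1.99 FPKM). Among ligands and receptors of the EGF, IGF and KIT families 12 of 22 were higher and 2 lower, with a median of 1.06 (percentiles 99.1 and 98.9), but its 9 members at 5 FPKM or more lay at percentile 71.02. The EGF receptor ligand gene tgfa went from 8.32 to 53.5 FPKM, whereas nrg1 was lower (12.7 to 4.45 FPKM). In the PI3K, mTOR, FOXO and Hippo list 20 of 33 genes were higher and 1 lower, with a median of 1.12 (percentile 99.8 by expression, 97.485 with length). The PI3K regulatory subunit gene pik3r1 (chromosome 5, 55205596 to 55230696) was at 4.70 and 54.7 FPKM. The inhibitor genes tsc1a (9.03 and 64.2 FPKM) and ptena (3.28 and 21.2 FPKM) were higher, as was the transcription factor gene foxo3a (4.65 and 26.7 FPKM), whereas tsc2 (4.18 and 4.03 FPKM), tsc1b (difference 0.57) and eif4ebp1 (difference -0.37) did not pass the 2-fold rule. After centring, 8, 7 and 14 genes of these 3 lists were higher and 4, 2 and 1 lower, and with the length trend removed as well 6, 3 and 11 were higher and 4, 2 and 1 lower.

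Cell cycle genes had a median of 0.18 over 35 members, at percentile 99.8 by expression and 88.5 with length, and the sign of that median turned to -0.23 after centring. The kinase gene wee1 (10.1 to 53.0 FPKM), top2a and mki67 were higher, and the cyclin gene ccnb1 (1775 to 683 FPKM) was lower. As deposited 4 genes of the list were higher and 3 lower, against 1 and 7 after centring, when top2a and mki67 no longer passed the 2-fold rule. After rescaling to the same FPKM total 7 were higher and 2 lower, and with mitochondrially encoded genes left out 8 and 1. Small RNA biogenesis genes had 9 of 18 higher and none lower, with a median of 0.95 (percentiles 95.8 and 64.3); with the length trend removed and genes centred, 3 were higher and the median was 0.17. The miRNA-processing enzyme gene dicer1 was at 2.94 and 17.98 FPKM, on a transcript of 9598 bases, and zswim8 at 16.2 and 65.3 FPKM. Yolk uptake genes had a median of 0.28 over 18 members (percentiles 86.1 and 42.4; negative after centring), with rab5aa higher (17.3 to 45.4 FPKM). Cholesterol and lipid genes had 10 of 23 higher (median 0.82, percentiles 86.1 and 63.1), among them dhcr7 and acaca. Extracellular matrix genes had 12 of 25 higher (median 0.99, percentiles 96.6 and 69.2), led by timp2a (1.09 to 15.2 FPKM). The list for junctions and cytoskeleton had 8 of 24 higher and 2 lower (median 0.63, percentiles 94.7 and 73.4). Among its lower genes was the claudin gene cldnd, at 3445 and 909 FPKM. After centring, 4, 7 and 3 genes of these last 3 lists were higher and 1, 0 and 3 lower. With the length trend removed as well 2, 3 and 3 were higher and 1, 1 and 4 lower, and the medians turned to -0.01, -0.15 and -0.11. Stress and immediate early genes had a median of 0.16 over 22 members (percentiles 7.56 and 14.5), with a sign that depended on scaling. Of these only dusp1 passed the 2-fold rule (61.2 to 173 FPKM).

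Markers of other cell types gave no common direction. The 4 erythrocyte markers measured had a median of -0.19 (percentiles 5.60 and 49.0) and none passed the 2-fold rule, with hbaa1 at 55.1 and 51.6 FPKM. Of 8 leukocyte markers 1 was lower, lyz, and the median was 0.37 (percentiles 28.0 and 43.0). The medians of both blood lists changed sign with scaling. Endothelial and mural markers had 6 of 14 higher and 1 lower (median 0.86, percentiles 83.5 and 88.5), including the smooth muscle genes acta2 (2.90 to 15.6 FPKM) and tagln (1.70 to 9.61 FPKM) and the endothelial receptor gene kdrl (0.981 to 4.13 FPKM). Of 4 testis markers 1 was lower, spata4 (median -0.46, percentiles 2.91 and 4.43). Of 22 names on the list of vitellogenins and liver transcripts 1 reached 1 FPKM, tfa, at 1.70 and 0.762 FPKM.

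**Figure D2:**
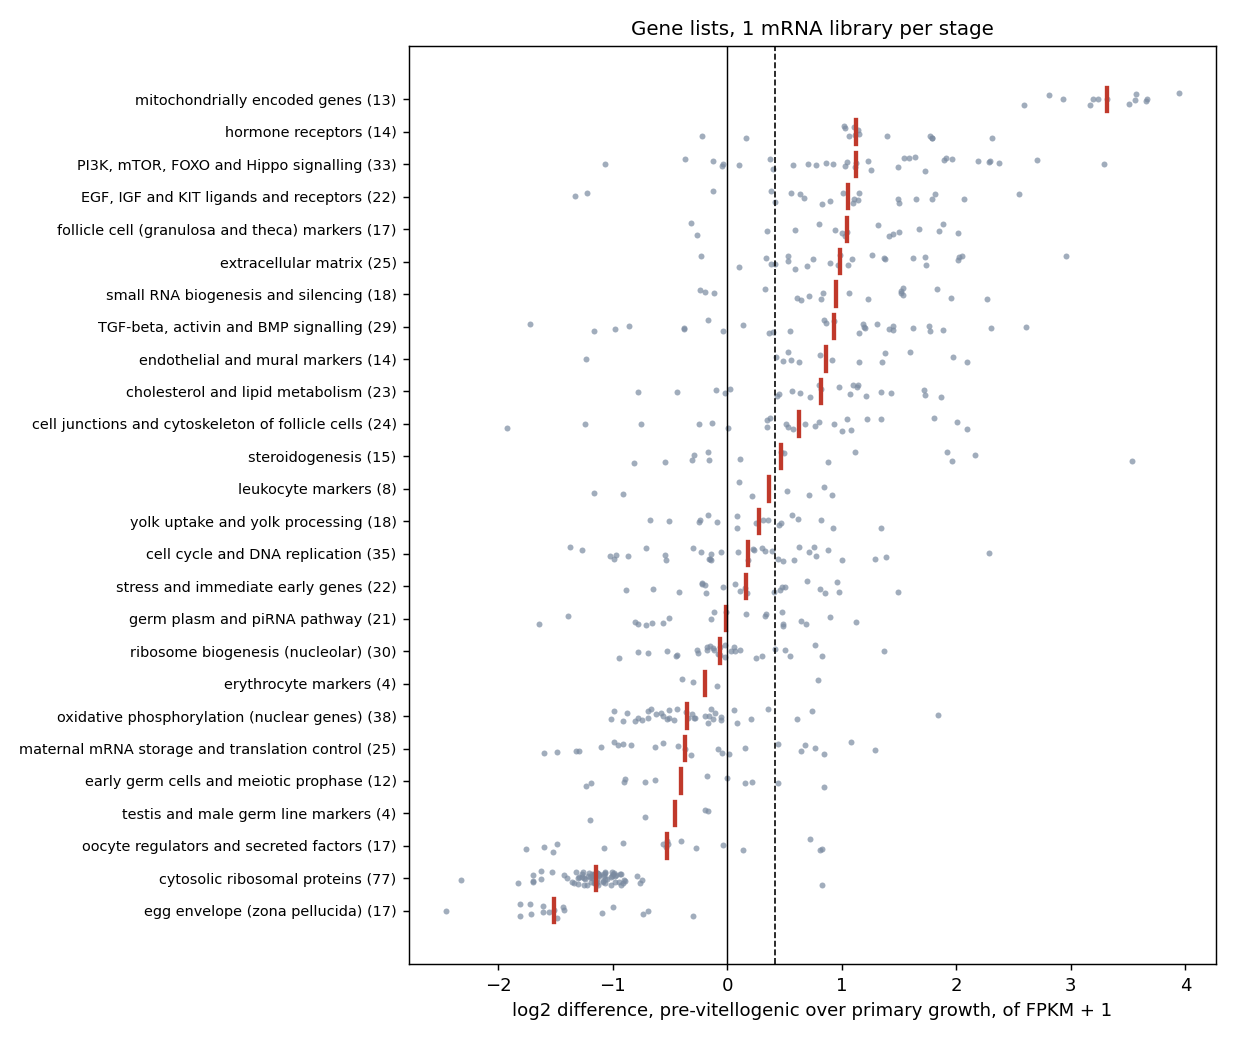
Log2 difference of FPKM + 1 (x axis, pre-vitellogenic over primary growth) for each member of 26 gene lists with 3 or more measured genes (points; number of genes in parentheses) and the list median (red bar). The solid line marks 0 and the dashed line the median of all genes at 1 FPKM or more in both libraries, 0.42; egg envelope and ribosomal protein genes sit at the low end and mitochondrially encoded genes at 3.32.

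The largest single differences rested mostly on very short transcripts. Of the 24 named for size, 18 had a length below 300 bases, a class that held 200 of the 14473 genes, and 13 were listed at 0 in 1 library. Small nucleolar and Cajal body RNAs made up most of these, SNORA32, SNORA70, SNORA36, SNORA50, SNORA69, SNORA68 and SCARNA14 being listed at 0 in pre-vitellogenic follicles, with the precursor dre-mir-96, and snoU6-53, SCARNA24, SCARNA8, dre-let-7a-5 and bglap at 0 in primary growth. The protein-coding genes cdk19 (50.2 to 0.0582 FPKM) and gpc3 on the lower side and agtpbp1 (0.0933 to 47.5 FPKM) and rims1a (0.515 to 51.2 FPKM) on the higher side had an abundance-weighted transcript length below 300 bases. With longer transcripts stood dynll1, a dynein light chain gene (chromosome 8, 2662318 to 2666539; 689.5 to 55.2 FPKM), on the lower side. On the higher side were angptl4, a lipoprotein lipase inhibitor (chromosome 2, 23321628 to 23327384; 1.40 to 53.2 FPKM), MFAP4 (8 of 14) and pdia2 (0.289 to 21.3 FPKM). The deposited intervals were wide: of 21775 transcripts at 1 FPKM or more with usable intervals, the lower bound was 0 for 90.1% in primary growth and 86.9% in pre-vitellogenic follicles.

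The second comparison asked which miRNAs differ between the stages. Values are in RPM, the reads of a miRNA per 1000000 of its library total, and what that total counts is not given. By that measure nearly all miRNAs were higher in pre-vitellogenic follicles, led by the let-7 family, miR-202-5p, miR-143, miR-218a and the miR-23 and miR-24 clusters. The listed miRNAs summed to 60483 reads, or 0.460% of the primary growth library (Wilson 95% interval 0.456% to 0.464%), and 606372 reads, or 3.18% of the pre-vitellogenic library (3.18% to 3.19%). The ratio of the summed RPM was 6.92 (exact conditional 95% interval 6.86 to 6.98). These intervals and those below cover counting error only and compare 2 libraries, not 2 stages. Of 27 miRNAs at 100 RPM or more in the higher library 25 were at least 2-fold higher, none was lower and 2 were neither, on the log2(RPM + 10) scale. Once both libraries were rescaled to the same miRNA total, 11 were higher, 4 lower and 12 neither. The RPM and the share of miRNA reads are therefore given together.

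Several miRNAs exceeded the 6.92-fold ratio of the total. The let-7 family, 12 miRNAs, summed to 354 and 7264 RPM (ratio 20.5, 19.9 to 21.1; 7258 RPM with the shared sequence of let-7c-3p and let-7d-3p counted once), from 7.69% to 22.8% of miRNA reads. Within it let-7a was at 301 and 5939 RPM. The gonadal miR-202-5p was at 62.4 and 1347 RPM (ratio 21.6, 20.1 to 23.2), from 1.36% to 4.23% of miRNA reads. The miR-23, miR-24 and miR-27 clusters summed to 23.96 and 817 RPM (ratio 34.1, 30.5 to 38.2), with miR-23a-3p at 7.07 and 423 RPM. The smooth muscle miRNA miR-143 was at 186 and 2596 RPM (ratio 14.0, 13.4 to 14.6), and miR-218a at 23.3 and 509.7 RPM. The most abundant miRNA of both libraries was miR-22a-3p, at 865 and 7339.8 RPM, with 18.8% and 23.1% of miRNA reads. Another abundant one, miR-21, was at 157 and 1494 RPM (ratio 9.51, 9.09 to 9.95).

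Other miRNAs were higher in RPM and lower as a share of miRNA reads. In primary growth follicles miR-100-5p was the second most abundant, at 851 RPM, and it reached 3210 RPM in pre-vitellogenic follicles, so its share went from 18.5% to 10.1%. The share of miR-20a-5p, a member of the miR-17 family, went from 12.4% to 2.89% (569.7 and 919 RPM; ratio 1.61, 1.57 to 1.66). That of miR-9-5p went from 3.89% to 0.836% (179 and 266 RPM; ratio 1.49, 1.42 to 1.56). These were the 2 miRNAs that did not reach the 2-fold mark. The shares of miR-92a-3p (5.05% to 2.23%) and miR-26a-5p (5.54% to 2.57%) were also lower by more than 2-fold after rescaling. The miR-181 family held 2.45% and 2.48% of miRNA reads.

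Of 65 miRNAs above 0 in both libraries, 4 had a lower RPM in pre-vitellogenic follicles. They were miR-430a-3p (21.4 to 7.77 RPM; ratio 0.364, 0.296 to 0.445), miR-375 (ratio 0.585, 0.427 to 0.8002), miR-725-3p (8.37 to 5.67 RPM; ratio 0.678, 0.515 to 0.892) and miR-194b (3.65 to 2.73 RPM), whose ratio of 0.748 (0.495 to 1.13) lay within counting error of 1. They lie below the level set for a call and were named after their values were seen. A further 42 miRNAs were listed at 0 in primary growth alone and 11 at 0 in pre-vitellogenic follicles alone. Among the 11, miR-7a was at 34.4 RPM, or 452 reads, in primary growth. No value above 0 corresponded to fewer than 6 reads in either library, so a value of 0 need not be a count of 0 reads, and no ratio of a single miRNA is given against it. Sums of lists take such values as 0, for 3 members of the let-7 list and 1 of the miR-23, miR-24 and miR-27 list in primary growth, and 5 reads for each would make these ratios 20.45 and 33.6.

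Among miRNAs that mark other tissues, miR-144-5p, the only listed miRNA of the erythrocyte list, was listed at 0 and was at 1.26 RPM. The leukocyte list summed to 0.608 and 10.7 RPM, with 2 of its 3 members listed at 0 in primary growth. The liver miRNA miR-122 was listed at 0 and was at 2.63 RPM. Counting once the sequence listed as both miR-126a-5p and miR-126b-5p, the endothelial miR-126 list summed to 18.2 and 85.9 RPM, and the mesenchymal miR-199 and miR-214 list to 23.8 and 81.1 RPM. The epithelial miR-200 and miR-141 list summed to 3.42 and 23.2 RPM and the miR-15 and miR-16 family to 13.4 and 149 RPM.

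**Figure D3:**
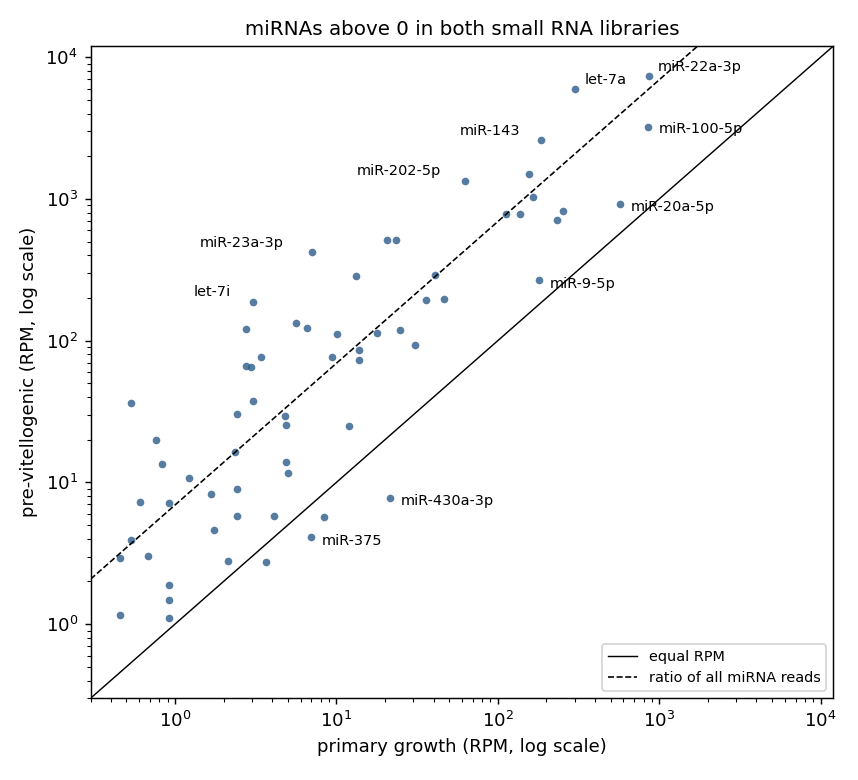
RPM of the 65 miRNAs above 0 in both libraries, in primary growth (x axis, log scale) and pre-vitellogenic follicles (y axis, log scale), 1 point per miRNA. The solid line marks equal RPM, below which 4 miRNAs lie, and the dashed line the 6.92-fold ratio of all miRNA reads, below which miR-100-5p, miR-20a-5p and miR-9-5p lie.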

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

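The length-based alternatives, the protein-coding one, the one without mitochondrially encoded genes, and those for values of 0 and shared sequences in miRNA lists were chosen after the data were seen; all others were fixed before. No paired analysis was possible because each stage had 1 library of each kind. The seed site alternatives were not run. Scaling decided the balance of calls. Of 4203 genes higher and 945 lower, centring on the median left 2193 and 1912, 75th percentile scaling 2493 and 1806, and a pseudocount of 5 FPKM 1961 and 495. Rescaling to the same FPKM total gave 5861 and 711. A 1.5-fold rule gave 6712 and 1902 and a 4-fold rule 693 and 129, by construction. Lower genes were 487 with the length trend removed and 541 with mitochondrially encoded genes left out, and higher genes were 1746 with the length trend removed and centred; the cause was not tested. For miRNAs, 25 higher and 0 lower became 11 and 4 after rescaling to the same total, 11 and 4 after rescaling without the most abundant miRNA, and 7 and 4 after centring, because these settings take out the common ratio. Without a filter 49 were higher and 2 lower, and 7 were higher at 1000 RPM or more, as more or fewer miRNAs were compared. Lists above the upper percentile mark numbered 6 and ranged from 4 to 9 across alternatives. With a pseudocount of 0.1 FPKM the follicle cell, small RNA and extracellular matrix lists were added, and with members at 5 FPKM or more the EGF, IGF and KIT list fell out (71.02) and small RNA came in (98.8). Lists below the lower mark numbered 4 and were 6 with length matched and 2 with members at 5 FPKM or more, where fewer genes entered and the meiotic prophase and nuclear oxidative phosphorylation lists no longer lay beyond it (percentiles 3.77 and 2.69).

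Among results past the 2-fold rule or a percentile mark, those that changed sign were as follows. Rescaled to the same total, without the most abundant miRNA, and centred, the differences were -1.16, -1.08 and -1.13 for miR-92a-3p, -1.09, -1.01 and -1.05 for miR-26a-5p, -0.64, -0.57 and -0.81 for miR-125b-5p, and -0.47, -0.40 and -0.81 for miR-125a. In the same order they were -0.87, -0.80 and -0.80 for miR-100-5p, -0.10, -0.036 and -0.55 for miR-26b, and -0.15, -0.072 and -0.13 for miR-99. The median of the cell cycle list was -0.23 after centring. Again the common ratio or shift is what these settings remove. Medians of lists that lay beyond no mark by expression matching changed sign too: after centring -0.43 for germ plasm, where rescaling to the same total gave 0.25, -0.14 for yolk uptake, -0.26 for stress and -0.05 for leukocyte genes. Rescaling to the same total gave 0.20 for nucleolar and 0.05 for erythrocyte genes, and removing the length trend with centring gave -0.01, -0.15 and -0.11 for cholesterol and lipid, extracellular matrix and junction genes. With members at 5 FPKM or more the median of steroidogenic genes was -0.16 (percentile 9.3). None of the named genes that passed the 2-fold rule, by the fixed rule or named later, changed sign under any alternative that gave them a value. Of those by the fixed rule 8 no longer passed it after centring, 15 with the length trend removed, 24 with it removed and centred, and 23 with a pseudocount of 5 FPKM. Of those named later 1 (si:ch211-226h8.14) no longer passed it with the length trend removed and 2 (bmp6 and nrg1) with a pseudocount of 5 FPKM. With length matching the hormone receptor, PI3K, cell cycle and nuclear oxidative phosphorylation lists no longer lay beyond a mark (percentiles 83.8, 97.485, 88.5 and 26.2). The oocyte regulator, germ plasm, maternal mRNA and follicle cell lists then did (0.38, 0.46, 0.115 and 97.9). Of 21 ratios of miRNA lists, 1 left its counting interval with shared sequences counted once (miR-126) and 1 with values of 0 in primary growth taken as 5 reads (leukocytes, 17.6 to 7.82). Depth of the mRNA libraries is unknown.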

Other observations

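Every test in this part was chosen after the result it concerns had been seen. Replication-dependent histone genes, a group chosen after its values were seen, were lower in pre-vitellogenic follicles. Of 17 measured genes named as clustered histones 14 were at least 2-fold lower and 1 was higher, among them HIST1H4A (49.96 to 5.796 FPKM) and hist1h2a11 (21.1 to 5.70 FPKM). The many near-identical copies of these genes make the split of reads between them uncertain. A second added selection took protein-coding genes at 1 FPKM or more in both libraries and 20 FPKM or more in the higher one. On the higher side it held the pseudokinase gene trib3 (3.44 to 44.0 FPKM), the polyamine enzyme gene sat1a.1 (2.08 to 36.7 FPKM) and the Hippo-linked gene amotl2a (4.46 to 55.3 FPKM). On the lower side it held 2 dynein light chain genes, dynll1 (689.5 to 55.2 FPKM) and dynll2b (101 to 18.8 FPKM), and gadd45g (44.0 to 8.15 FPKM).

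Small RNA values held further irregularities. The reads of 55 of 76 miRNAs above 0 in primary growth and of 71 of 107 in pre-vitellogenic follicles were even numbers. The reason is unknown; reads counted more than once would shift the shares of miRNA reads and make the counting intervals too narrow. Mature sequences listed under more than 1 name numbered 2. Of the miR-199 rows, miR-199-3p was at 14.4 RPM and then listed at 0, while miR-199-3-3p was listed at 0 and then at 3.41 RPM.

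The first pattern weighed is the excess of genes higher in the pre-vitellogenic library, 4.45 for each gene lower. If a few abundant genes taking a larger share of the primary growth library were the whole cause, leaving them out should even the ratio. It was 8.24 with all genes rescaled to the same FPKM total and 5.53 on genes other than the 100 most abundant, lower and not even. That test covers those 100 genes only. Centring on the median left 2193 genes higher and 1912 lower, and 75th percentile scaling 2493 and 1806, both closer to even. A wider shift in the make-up of the libraries thus cannot be excluded. The trend with transcript length cannot be told apart from the excess, because the overall level decides the outcome: with the trend removed the ratio was 7.93 with the overall median kept and 1.32 with it set to 0. In the shortest bin of length 23.8% of genes were lower and 18.1% higher, and in the longest 0.364% and 61.9%. RNA integrity and fragment size are not given in the sources used here, and a larger contribution of follicle cells at the later stage stays open and untested.

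The second pattern is the higher level of all 13 mitochondrially encoded genes. They lay 3.22 log2 units above the median of 7790 other genes in their range of transcript length, which argues against the length trend. Carry-over of more RNA without a poly(A) tail would bear on these genes only if their RNA lacked such a tail, which was not examined. Whether poly(A) selection was used is not known either. The RNAs without a tail that were looked at moved apart. They therefore cannot tell carry-over from a change in the follicles. Histone genes had a median of -2.14 and the signal recognition particle RNA a difference of -2.67, but 5S rRNA had 0.73 and 5.8S rRNA 4.48. The 2 transcripts of the mitochondrial genome outside its 13 coding genes, with 3.84 and 2.48, belong to the same rise. They are no separate check on it. More mitochondrial transcripts per follicle at the later stage may underlie the pattern, but FPKM is a relative measure and cannot show this. Mitochondrial DNA was not analysed here.

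The third pattern is the 6.92-fold higher share of miRNA reads in the library total, which does not give an amount per follicle. Of 29 miRNAs with 100 or more reads in both libraries, 24, or 82.8%, had a counting interval that missed the common ratio, and their ratios ran from 0.364 to 24.6. Uniform dilution by other small RNAs in the primary growth library nevertheless cannot be told apart from a change in the follicles, because the variation of single miRNAs between libraries of 1 stage is unknown. More erythrocytes in the pre-vitellogenic follicles would bring erythrocyte mRNAs, whose median difference was -0.19 and highest 0.79. These markers are 4 genes of the mRNA libraries, so they do not measure blood in the small RNA libraries. There miR-144-5p, the only listed miRNA of the erythrocyte list, was listed at 0 and then at 1.26 RPM. For leukocytes the marker median was 0.37, below the shift of 0.42 over all genes. Their miRNA list summed to 0.608 and 10.7 RPM, a ratio of 7.82 with values of 0 taken as 5 reads. It held 0.0336% of pre-vitellogenic miRNA reads, so the listed leukocyte miRNAs themselves add little to the rise. Leukocytes as a source of other miRNAs stay open, their markers being low in both libraries. A change in the miRNAs of oocytes or follicle cells, which these libraries do not separate, stays open too.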
